A study of Mus musculus with 2 samples.

How the data were processed

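Small RNA sequencing of microRNAs (miRNAs) was analysed for adrenal glands of male mice on postnatal day 4. Per the labels, the animals were B6CASTF1/J mice, the offspring of a cross between the laboratory strain C57BL/6J and the wild-derived strain CAST/EiJ, total RNA was used, and the sequenced size range was under 30 nucleotides. The series held 1 group with 2 libraries. Per the labels these were biological replicates 1 and 2, each with technical replicate 1, from males numbered 3 and 4. Both entries carried the same donor label, so the 2 libraries were taken as 2 animals from the numbers of the males alone. No second group was present, and no comparison between conditions was made.

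The deposited tables held whole-number read counts per miRNA gene, with 1 table per library. Each table had 3 count columns and 4 summary rows for reads not given to a gene. Per the file lists deposited beside them, the tables were made on mouse genome build mm10 with annotation release M21. The summary rows and columns had the layout of the gene counts written by STAR. The aligner, its version, the trimming of adapters and the filters on reads were not given in the sources used here. All 2202 gene identifiers matched the GENCODE M21 annotation, and all were annotated there as miRNA genes. Gene symbols, positions and neighbouring genes were taken from that annotation, with coordinates on mm10 counted from 1. A miRNA gene was placed in an exon if it overlapped an exon of any annotated transcript of its host gene. It can lie in an intron of other transcripts of that host.

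The first count column covered reads of either strand, and the other columns covered 1 strand each. The file lists named no column for quantification. By a rule set beforehand, the strand column with more counts was used, and it is called the sense strand here. The either-strand column gave few or no counts to miRNA genes that overlap on opposite strands. Among 64 miRNA genes with another miRNA gene annotated on the other strand, 27 had at least 10 sense-strand counts in both libraries, and all 27 had under 10 counts in the either-strand column. These 64 genes held 12.1% of the sense-strand counts in replicate 1 and 12.8% in replicate 2.

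A count belonged to a precursor gene, so the mature forms from its opposite arms were not told apart. Reads that aligned to more than 1 locus were set aside in a summary row in the deposited tables. Several miRNAs are made in identical mature form from more than 1 locus, and the counts of such loci are therefore uncertain. The summary rows were left out of library totals. Reads that aligned to more than 1 locus, outside miRNA genes or nowhere made up 66.3% of replicate 1 and 74.3% of replicate 2.

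Levels were expressed as counts scaled to a library total of 1000000 sense-strand miRNA counts (CPM), or as the same share in percent. Means are given with the standard deviation (SD) over the 2 libraries. A gene was called detected with at least 10 counts in both libraries. Shares within 1 library have exact Clopper-Pearson 95% intervals. A count of 0 allowed a level of up to 3 counts, which was 0.757 CPM in replicate 1 and 1.78 CPM in replicate 2. Sequencing reads are not independent molecules, so intervals, limits and the exact test covered counting error only.

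Genes that differed between the libraries were sought with a two-sided exact binomial test per gene of its counts against the ratio of the library totals. Genes with at least 10 counts in either library were tested. A gene was called different at a Benjamini-Hochberg adjusted p under 0.05 together with a log2 ratio of replicate 2 over replicate 1, taken on CPM + 0.5, above 1 or below -1. This test compared the 2 libraries, not conditions. The spread between libraries was estimated with the common dispersion of edgeR 4.0.16 in a model with an intercept only, after scaling by the trimmed mean of M-values (TMM). Size factors from DESeq2 1.42.0 served as another scaling. The analyses ran in R 4.3.3 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

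In all, 21 lists of miRNA genes were fixed before the data were examined, as were the tests, the thresholds and the rule for named genes. The lists covered the let-7 family, neuroendocrine cells, neurons, miRNAs linked to adrenocortical function, the Dlk1-Dio3 cluster, other imprinted loci, the X-linked cluster of Mir322 and Mir503, the miR-17/92 clusters and the Hox clusters. Cell and tissue lists covered endothelium, erythroid cells, leukocytes, smooth muscle and stroma, striated muscle, liver, kidney, epithelium, brown fat, pancreatic acinus, and ciliated and germ cells. A last list held loci that share a mature form. List symbols that matched no gene were left out, and member counts cover the matched genes only. Such symbols numbered 2 for liver, 3 for erythroid cells, 3 for neurons, 4 for Dlk1-Dio3 and 7 for shared mature forms, with fewer or equal numbers in some other lists. The median log2 ratio of each list was set among 10000 random lists of the same size matched on mean level, as a description of these libraries. The named genes were the 25 with the highest mean CPM, the 4 highest members of each list, and the 5 with the largest log2 ratio in each direction among called genes with a mean CPM of at least 10. Genes named outside this rule are marked as chosen after their values were seen.

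The exact test was checked on counts simulated for 407 genes. It recovered 94.2% of 104 genes changed by 3-fold and 99.0% of 96 genes changed by 4-fold, and it called 1 of 207 unchanged genes. These simulated counts held counting error only, and the true totals were given to the test. The check therefore says nothing about false calls from spread between animals or from scaling. On counts simulated for 340 genes, edgeR returned a dispersion of 0.0484 where 0.05 had been used and 0.194 where 0.2 had been used. Alternatives covered the count column, the count minimum, the depth, the scaling, the added CPM, the size threshold and each library left out. Removal of a trend with precursor GC content, and a set of genes that share no 20 bases with another precursor, were added after the data had been seen. Levels and shares were classed as unchanged within their SD. List medians were so classed when they stayed inside or outside the central 95% of random lists. Gene counts and the edgeR spread have no SD or threshold here and were classed by closeness to the main value. Thus 269 genes with at least 50 counts in both libraries were classed as unchanged against 340 detected genes. So were 57 calls with CPM + 5 against 74.

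For the closing section, 4 tests of explanations were set out beforehand and 4 afterwards. The cut-offs of those 4 later tests were written when their values were already known. The families compared in the test of shared mature forms were also put together after the levels had been seen. A further test, of dilution by RNA from another tissue, was run on the genes called lower in replicate 2 and left out, since the calling threshold itself fixed its outcome. The first test of GC content, the share of calls left after its trend was removed, was also dropped, because the removal moved the median gene by a log2 ratio of only 0.03. The share of variance that GC content accounts for took its place, with 10000 bootstrap draws over genes.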

Results

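MicroRNA levels were measured in adrenal glands of 2 male mice on postnatal day 4. The adrenal gland joins a steroid-producing cortex to a medulla of catecholamine-producing chromaffin cells, and the cortex is still being remodelled in the first days after birth. The labels describe an evaluation of RNA from this tissue and state no comparison. The values below therefore describe which miRNA genes were counted, at which level, and how far the 2 libraries differed. Each animal gave 1 library, so differences between animals, dissections and library preparations cannot be told apart. Replicate 1 had 11770895 reads and replicate 2 had 6557080 reads.

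Reads on the sense strand of miRNA genes numbered 3961630 in replicate 1, or 33.7% of its reads (95% exact interval 33.6 to 33.7%). In replicate 2 they numbered 1686822, or 25.7% (25.7 to 25.8%). The mean share was 29.7% ± 5.61 (SD, n = 2). Reads that aligned to more than 1 locus made up 27.0% of replicate 1 and 25.7% of replicate 2. Unaligned reads made up 32.4% and 39.1%, and reads outside miRNA genes made up 6.93% and 9.52%, in the same order. The lower depth of replicate 2 gave it wider counting error for genes of low level.

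**Figure D1:**
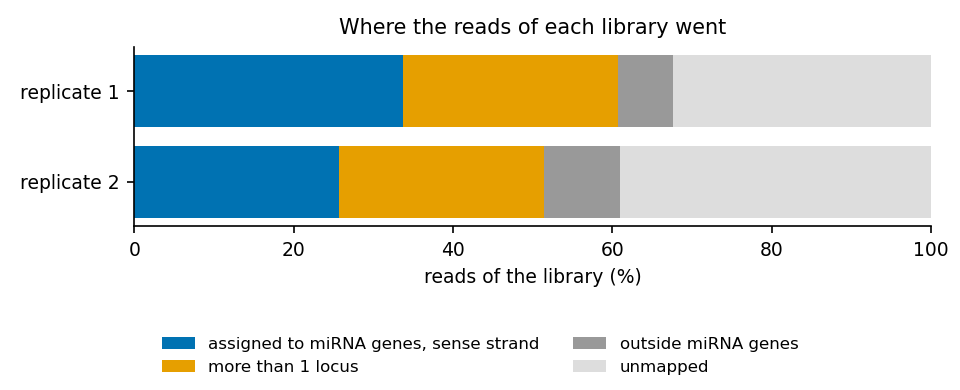
Share of the reads of each library (x axis, %) by where they were assigned, with 1 bar per library. Sense-strand miRNA reads took 33.7% of replicate 1 and 25.7% of replicate 2.

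By mean level over both libraries, the counts were led by Mir126a, a miRNA of endothelial cells, and by members of the let-7 family. Members of this family rise as tissues mature. In replicate 1 Mirlet7g and Mir10a lay above Mir126a. Reads that aligned to more than 1 locus, 3176275 in replicate 1 and 1684373 in replicate 2, were outside this ranking. A miRNA made from several loci, or one that shares sequence with another, could therefore rank higher than shown. Mir126a held 7.43% ± 1.28 of miRNA counts (SD, n = 2), Mirlet7g 6.84% ± 0.391 and Mirlet7i 6.29% ± 0.0977. Next came Mir10a, which lies in a Hox cluster, with 5.93% ± 0.892, and the X-linked Mir322 with 4.36% ± 1.31. Mir143 of smooth muscle and stroma held 3.98% ± 0.256, and Mir375, a miRNA of endocrine cells, held 3.68% ± 0.795. Of the 2202 annotated miRNA genes, 340 were detected and 1445 had no count in either library.

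A small number of genes made up most of the counts. The 10 most abundant genes held 47.8% ± 0.496 of the counts (SD, n = 2), the top 25 held 74.3% ± 0.326, and the top 100 held 95.7% ± 0.0712. A mean of at least 10000 CPM was reached by 23 genes and a mean of at least 1000 CPM by 92 genes. Mir126a (gene ENSMUSG00000065540.1) lies at chromosome 2, 26591357 to 26591429, within Egfl7, where it overlaps an exon of an annotated transcript. Mirlet7g lies at chromosome 9, 106178840 to 106178927, in an intron of Wdr82. Mirlet7i lies at chromosome 10, 122985640 to 122985724, where it overlaps an annotated exon of the noncoding gene D630033A02Rik. Mir10a lies between annotated genes at chromosome 11, 96317165 to 96317274. Mir322 lies between annotated genes at chromosome X, 53054255 to 53054349.

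The rest of the 25 most abundant genes ranged from Mir26b, in an intron of Ctdsp1, with 3.37% ± 1.26 (SD, n = 2), to Mir30d with 0.903% ± 0.000938. Mir23b held 3.08% ± 0.750 and Mir23a 2.33% ± 0.716. Both share 20 bases with another precursor, as do Mir411 and Mir378a, so the levels of these genes are uncertain. Mir21a, which overlaps an exon of an annotated transcript of Vmp1, held 2.83% ± 1.60. Mir411, Mir127 and Mir379 of the imprinted Dlk1-Dio3 region held 2.75% ± 0.183, 1.63% ± 0.115 and 1.56% ± 0.210. Mir335, in an intron of the imprinted gene Mest, held 2.59% ± 0.438. Mir99a held 2.33% ± 0.0747, Mir10b in an intron of Hoxd3 held 2.27% ± 0.963, Mirlet7d held 2.04% ± 0.496 and Mirlet7b held 1.85% ± 0.0620. Mir139 held 1.80% ± 0.0887, Mir378a in an intron of Ppargc1b held 1.31% ± 0.0152, Mir744 held 1.14% ± 0.252 and Mir130a held 0.960% ± 0.514. Mir122, the main miRNA of hepatocytes, held 1.10% ± 1.36 and was the only one of the 25 whose SD exceeded its mean.

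**Figure D2:**
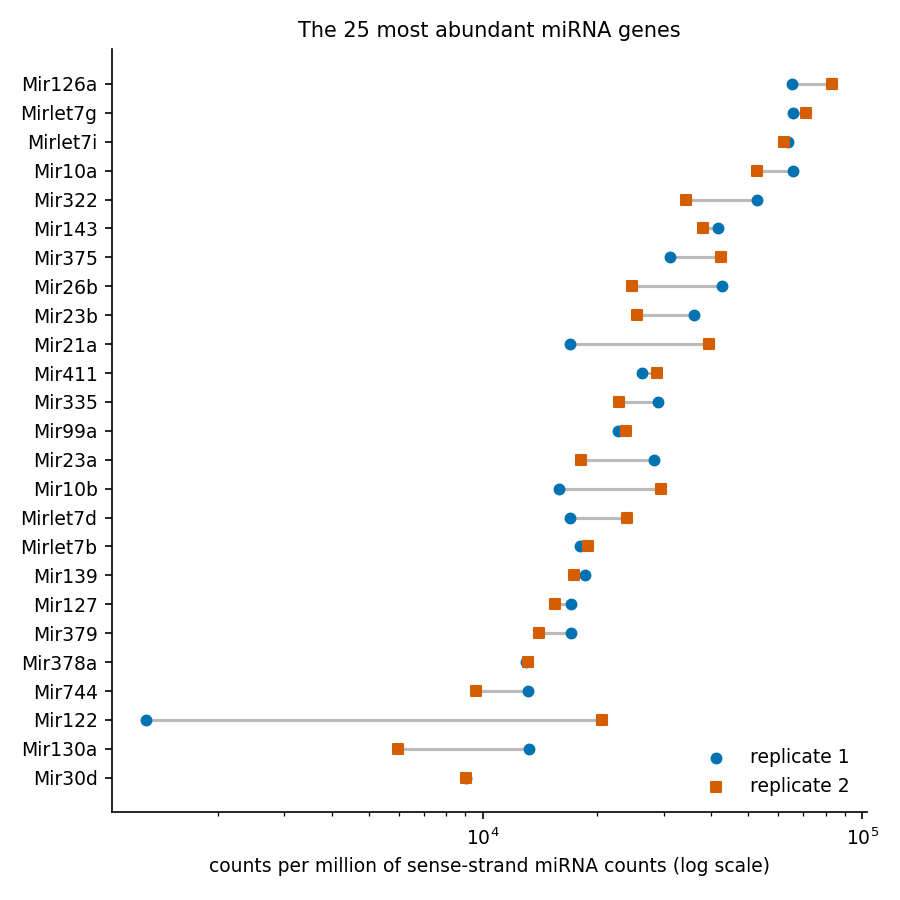
Level of the 25 most abundant miRNA genes in CPM (x axis, log scale), with 1 point per library joined by a line. Mir122 spans the widest gap, from 1299 CPM in replicate 1 to 20602 CPM in replicate 2.

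The let-7 family was the most abundant of the lists, with 19.0% ± 1.31 of miRNA counts (SD, n = 2) and all 12 members detected. The Dlk1-Dio3 region, a maternally expressed cluster of miRNAs that is active in fetal and endocrine tissue, held 12.0% ± 0.00466, with 50 of 58 members detected; its SD of 46.6 CPM was 6338 CPM under TMM scaling. Hox cluster miRNAs, which mark position along the body axis, held 8.40% ± 0.0497 (SD 497 CPM, and 3913 CPM under TMM scaling), led by Mir10a and Mir10b, with Mir615 at 1004 ± 20.8 CPM and Mir196b at 775 ± 178 CPM. The X-linked cluster of Mir322 and Mir503 held 5.28% ± 1.20, of which Mir351 gave 6842 ± 1215 CPM and Mir503 gave 896 ± 43.7 CPM. Other imprinted loci held 2.99% ± 0.211, led by Mir335 and then Mir298 with 2566 ± 2364 CPM. The growth-linked miR-17/92 clusters held 1.23% ± 0.316, led by Mir17 with 4044 ± 846 CPM and Mir93 with 2712 ± 901 CPM.

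Neuroendocrine miRNAs held 4.20% ± 0.716 of the counts (SD, n = 2), with all 7 members detected. Mir375 made up most of this, ahead of Mir7b with 4162 ± 577 CPM, Mir7-1 with 467 ± 7.04 CPM and Mir182 with 319 ± 181 CPM. Neuronal miRNAs held 0.129% ± 0.0305, with 9 of 18 members detected, and the highest was Mir137 with 827 ± 212 CPM. MiRNAs linked to adrenocortical function held 4.01% ± 1.83 with all 12 members detected, led by Mir21a, then Mir125a with 5654 ± 1320 CPM and Mir214 with 2716 ± 757 CPM.

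Among the lists for other cell types, endothelium held 7.43% ± 1.29 (SD, n = 2), which was Mir126a apart from 5.45 ± 2.35 CPM of Mir126b. Smooth muscle and stroma held 4.32% ± 0.198, led by Mir143. Erythroid miRNAs held 0.392% ± 0.470, leukocyte miRNAs 0.177% ± 0.0599 and epithelial miRNAs 0.113% ± 0.0270. Liver held 1.10% ± 1.36 from Mir122 alone. Striated muscle held 0.192% ± 0.110, nearly all from Mir206 with 1888 ± 1072 CPM. Ciliated and germ cell miRNAs held 0.137% ± 0.0948, led by Mir34c with 1242 ± 939 CPM. Kidney held 0.0310% ± 0.00974, brown fat 0.00734% ± 0.000903 and pancreatic acinus 0.00106% ± 0.00143.

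Loci that share their mature form with another locus held 1.26% ± 0.0813 of the counts (SD, n = 2) over 62 loci, of which 42 were detected. The highest were Mirlet7f-2 with 4123 ± 865 CPM, Mir16-1 with 1554 ± 392 CPM, Mir92-1 with 1160 ± 127 CPM and Mirlet7c-2 with 531 ± 119 CPM. Reads that fit several loci were not in these counts, so the levels of the miRNAs concerned are uncertain.

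**Figure D3:**
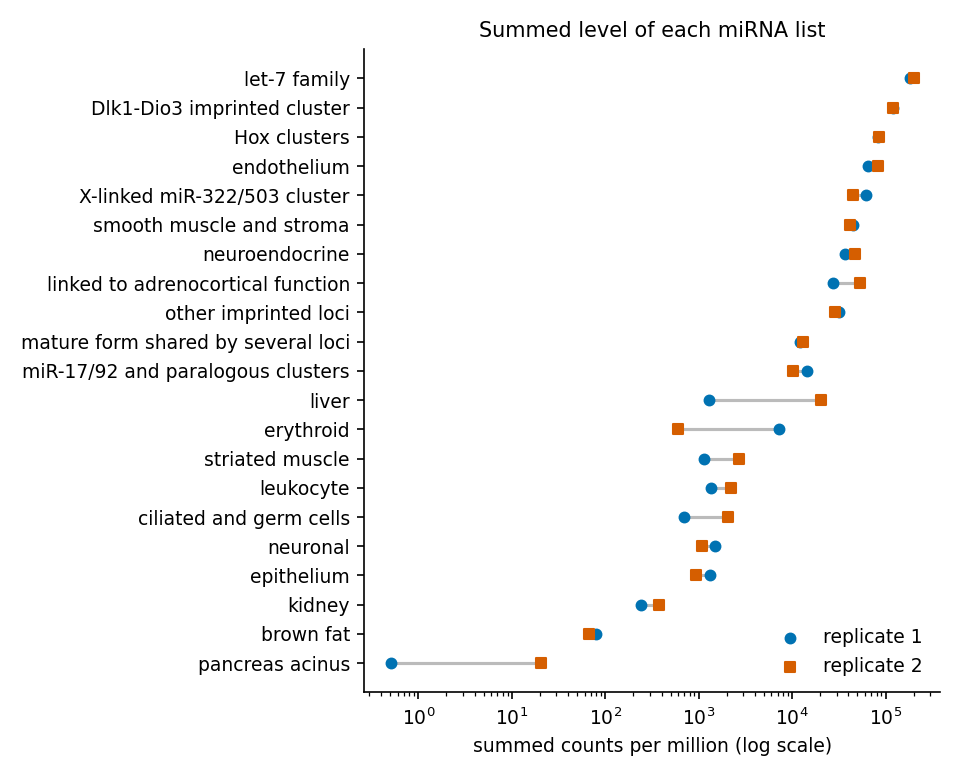
Summed level of each miRNA list in CPM (x axis, log scale), with 1 point per library joined by a line. The let-7 family reached 180751 CPM in replicate 1 and 199269 CPM in replicate 2, while the erythroid list was at 7248 and 595 CPM.

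The libraries of the 2 animals shared the same broad profile and differed in single genes, among them markers of liver, red blood cells and muscle. Mir122 of hepatocytes was 15.9-fold higher in replicate 2 (95% exact interval 15.4 to 16.3), with 5145 and 34752 counts. Mir451a, a miRNA of red blood cells, was 13.9-fold lower in replicate 2 (13.0 to 15.0), with 27106 and 828 counts. In all, 74 of 404 tested genes were called different by the exact test, 39 of them higher and 35 lower in replicate 2.

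Among genes with a mean CPM of at least 10, the 5 largest differences toward replicate 2 were those of Mir122 (log2 ratio 3.99), Mir26a-1 (2.98), Mir31 (2.80), Mir499 (2.32) and Mir298 (2.24). Mir31 lies at chromosome 4, 88910557 to 88910662, and had 427 and 1273 counts. Mir499, in an intron of the muscle myosin gene Myh7b, had 28 and 63 counts (adjusted p = 3.61e-14, exact test). Mir298 had 3544 and 7149 counts. Mir26a-1 had 98 and 336 counts, and it shares its mature form with Mir26a-2, so its level is uncertain.

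Toward replicate 1, above the same mean CPM, the 5 largest differences were those of Mir215, Mir301 (log2 ratio -4.50), Mir153 (-4.39), Mir451a (-3.80) and Mir200b (-3.07). Sizes and order depended on the added CPM. With CPM + 5, Mir215 went from -6.06 to -3.79 and Mir153 to -3.56, and Mir301 (-4.47) was the largest of these 5. Mir301, at chromosome 11, 87113004 to 87113089 in an intron of Ska2, had 17778 counts in replicate 1 and 334 in replicate 2. Mir215 had 287 counts and 1 count, a ratio of 122 with an exact interval from 21.8 to 4843. Mir153, in an intron of the neuroendocrine gene Ptprn2, had 434 and 8 counts. Mir200b, an epithelial miRNA, had 1078 and 54 counts.

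By list, the erythroid members Mir451a and Mir144 were lower in replicate 2 and Mir486 was not called. The list median of -2.21 lay at percentile 0.1 of random lists. Of 4 striated muscle members tested, Mir206, Mir499 and Mir208b were higher (list median 1.27, percentile 99.6), and Mir1b had 13 and 2 counts. In the either-strand column the striated muscle median lay at percentile 97.0, inside the central 95%. The liver list, with 1 gene, lay at percentile 100. Pancreatic acinus also lay at percentile 100 from Mir217 alone, with 2 and 32 counts, a ratio of 37.6 (exact interval 9.59 to 324). Of 5 kidney members, Mir192 and Mir194-2 were higher, Mir215 and Mir194-1 (chosen after its values were seen) were lower, and Mir204 was not called (list median 0.10, percentile 64.3; -0.01 under TMM scaling). Epithelial miRNAs had a median of -0.77 (percentile 0.6), with Mir200b and Mir200c lower and 5 members not called. Leukocyte miRNAs had a median of 0.55 (percentile 95.1), with Mir223 higher and 4 members not called.

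Of 12 members of the list linked to adrenocortical function, 2 were higher in replicate 2, among them Mir21a (log2 ratio 1.22), and the list median was 0.44 (percentile 98.2). No let-7 member of 12 was called, although the list median of 0.45 lay at percentile 99.1 (96.6 in the either-strand column, inside the central 95%). The miR-17/92 clusters had a median of -0.57 (percentile 0.66), with 3 of 14 members lower. Random lists were drawn gene by gene, whereas genes of 1 cluster had like ratios (intraclass correlation 0.442). This percentile, and those of other lists with clustered genes, may therefore be too extreme. In the Dlk1-Dio3 region 2 members were higher, among them Mir487b (1.22), and 3 were lower of 51 tested (median -0.06, percentile 52.6). Other imprinted loci had 2 members higher, Mir298 and Mir483, and 2 lower of 5 tested (median -0.35, percentile 20.7). Neuroendocrine miRNAs had 2 of 7 lower (median -0.01, percentile 54.8), and neuronal miRNAs had 1 higher and 2 lower of 11 (median -0.12, percentile 22.9).

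No member was called in the X-linked cluster of Mir322 and Mir503 (median -0.18, percentile 31.0), the Hox clusters (-0.07, percentile 47.5), endothelium (0.59, percentile 84.4), smooth muscle and stroma (-0.13, percentile 37.9) or brown fat (0.66, percentile 85.5). Of 3 ciliated and germ cell members, Mir34c was higher (median 0.26, percentile 67.4). Loci with a shared mature form had 6 higher and 4 lower of 47 (median 0.00, percentile 51.3). Adjusted over the list alone, the number of called members was the same in each of the 21 lists.

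**Figure D4:**
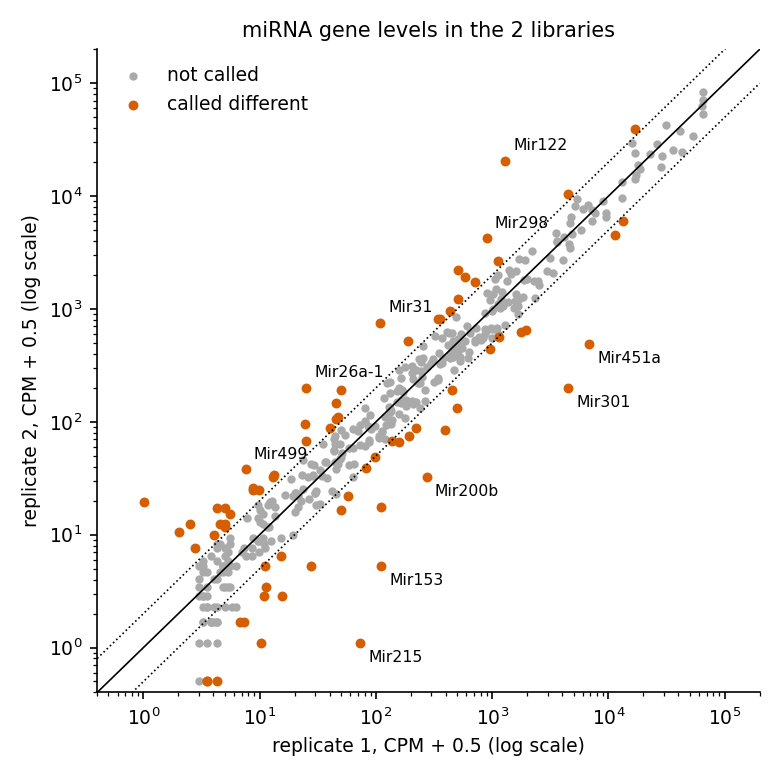
Level of each tested miRNA gene in replicate 1 (x axis) and replicate 2 (y axis), as CPM + 0.5 on log scales; coloured points are the 74 genes called different. The solid line marks equal levels and the dotted lines a log2 ratio of 1 in either direction.

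Across tested genes, log2 CPM correlated between the libraries with a Pearson r of 0.961 and a Spearman rho of 0.964; genes are not independent replicates. The median size of the log2 ratio was 0.50. The edgeR common dispersion was 0.155, a biological coefficient of variation of 0.394 over 340 genes. TMM scaling moved log2 ratios by -0.107, or by less for genes near the added 0.5 CPM, after which 79 genes were called, among them all 74. With 2 libraries of 1 group, a gene's difference has no replicate check.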

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

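No explanation was weighed in this part, and the restriction to genes with no annotated partner on the other strand was chosen after the data had been seen. Reads on the strand opposite to a miRNA gene were not used in the report. At 2 genes with no miRNA gene annotated on the other strand, they exceeded in both libraries the 3 counts that a count of 0 allows. The strand opposite to Mir203, a miRNA of skin and other epithelia at chromosome 12, 112130880 to 112130955, had 60 counts in replicate 1 and 44 in replicate 2. These were 2.84% and 4.39% of its sense-strand counts. The strand opposite to Mir708, at chromosome 7, 96249424 to 96249532, had 14 counts in replicate 1 and 7 in replicate 2, or 0.373% and 0.938% of its sense-strand counts.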

How the results depend on the processing

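The GC trend and the set without shared sequence were chosen after the data had been seen. With 2 libraries, leaving 1 out cannot move a list level by more than its SD, so those 42 alternatives show nothing about stability: in replicates 1 and 2 the liver list was at 1299 and 20602 CPM, erythroid at 7248 and 595, pancreatic acinus at 0.505 and 20.7, ciliated and germ cells at 696 and 2037, and striated muscle at 1146 and 2699. Of the other 236 alternatives for the main results, 210 were classed as unchanged (loosely so for gene counts), 24 as moved and 2 as weaker. Many of those 210 could hardly have moved, so the tally says little about stability. TMM and DESeq2 scaling shifted nearly all log2 ratios alike (by -0.107), so a list and its random lists moved together. The TMM factors of 0.964 and 1.04 nearly cancelled in a mean over both libraries. Removal of the GC trend moved the median gene by a log2 ratio of only 0.03. Staying within the spread says little for the liver, erythroid and pancreatic lists, whose SD exceeds their mean; the pancreatic list went from 10.6 to 0 CPM with at least 10 counts in both libraries. No list median beyond the central 95% of random lists changed sign. Medians near 0 did: kidney from 0.10 to -0.01 under TMM and DESeq2 scaling, Dlk1-Dio3 from -0.06 to 0.03 and shared mature forms from 0.00 to 0.03 in the either-strand column, and without the GC trend neuroendocrine from -0.01 to 0.01 and shared mature forms by under 0.01. Detected genes numbered 562 with at least 1 count in both libraries. The share of the 10 most abundant genes was 49.2% in the either-strand column, 46.5% without Mir126a and 48.2 to 49.3% with either library left out, since each library ranks its own genes. The either-strand column, which drops genes that overlap on opposite strands, gave summed levels of 208228 CPM for let-7, 124445 for Dlk1-Dio3, 34184 for other imprinted loci, 95922 for Hox clusters, 49361 for smooth muscle and stroma, 83.8 for brown fat and 13820 for shared mature forms. Endothelium had 1.68 CPM there, since Mir126a overlaps Mir126b, and erythroid miRNAs had 272 CPM against 3921, since Mir451a overlaps Mir451b, so that the erythroid median rested on 1 gene. Dlk1-Dio3 was at 119905 CPM under TMM (SD 6338) and under DESeq2 scaling (SD 6348), against 119821 ± 46.6 CPM. TMM also changed the SD of let-7 from 13094 to 3126 CPM, of shared mature forms from 813 to 154, of smooth muscle and stroma from 1976 to 4247 and of other imprinted loci from 2112 to 3685. In the either-strand column the list median of let-7 was 0.46 (percentile 96.6) and that of striated muscle 1.33 (percentile 97.0), both then inside the central 95% of random lists. Genes called different numbered 132 (66 higher, 66 lower) at a log2 ratio over 0.58, 251 (120 higher, 131 lower) at any size, and 49 (25 higher) without shared sequence, where 308 genes were tested. With at least 50 counts in either library 25 genes were higher and 26 lower, and under TMM 39 were higher and 40 lower. With no count filter the biological coefficient of variation was 0.435; the cause was not tested. Thinning replicate 1 to the total of replicate 2 lowered its genes with at least 10 counts from 400 to 339, and 325 were then detected in both; what the depth of replicate 2 itself left out was not measured. No paired analysis was possible because there was 1 group.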

Other observations

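Of the tests in this part, those of precursor GC content, co-transcribed neighbours, counting error by way of neighbours, and mature sequence, and their cut-offs, were chosen only after the result was seen. The first paragraphs name genes chosen after their values were seen. Several miRNAs of the miR-290 and miR-302 clusters, known from embryonic stem cells, had reads at low level in both libraries. With no other tissue or control library, the source of these reads was not tested. Mir293, at chromosome 7, 3220343 to 3220422, had 708 and 183 counts, a mean of 144 ± 49.7 CPM (SD, n = 2). Mir294 had 117 ± 19.7 CPM and Mir292 had 90.1 ± 22.6 CPM. Other members of the miR-290 cluster were lower, among them Mir295 with 18 and 3 counts, Mir290a with 15 and 2, and Mir292b with none. On chromosome 3, Mir302d had 59.7 ± 29.9 CPM, Mir302a 47.7 ± 22.2 CPM and Mir302b 39.2 ± 25.2 CPM, while Mir367 of the same cluster had 1 count and no count. Mir302b and Mir302d were called lower in replicate 2 (log2 ratios -1.40 and -1.06).

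Neighbouring miRNA genes did not always differ in the same direction between the libraries. Mir298 had a log2 ratio of 2.24 and Mir296, on the same strand of chromosome 2, had -1.02. Mir99b had -1.34, beside Mirlet7e with 0.32 and Mir125a with 0.48. On chromosome 1, Mir215 and Mir194-1 were lower in replicate 2 with 1 count each, while on chromosome 19 Mir192 (1.93) and Mir194-2 (1.98) were higher. Mir23a, Mir27a and Mir24-2 had like ratios of -0.64, -0.54 and -0.52. Within the Dlk1-Dio3 region, 47 genes with at least 50 counts in both libraries ranged from -1.58 to 1.22 with an SD of 0.556, against a counting error of 0.0654 for the median gene.

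Loci that share their mature form had low counts beside single-locus members of the same seed families. The median was 98.4 CPM over 36 shared loci and 1467 CPM over 31 single loci, a 14.9-fold gap (20.1-fold in replicate 1 and 19.9-fold in replicate 2), and shared loci summed to less in 14 of 15 families (exact signed-rank p = 0.000183, two-sided). In the let-7 family, 6 shared loci gave 0.563% of counts and single loci 18.4%. Reads fitting several loci were left out of the counts, which is a candidate explanation for the gap. That rule lowers shared loci by itself and made the direction of the gap likely in advance, so the signed-rank test adds little. The families were assembled after the levels were known, and Mir29c, Mir107 and Mir133b of the single set share 20 bases with another precursor. Lower transcription of these loci was not tested and stays open.

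Markers of other tissues differed between the libraries. Of 4 lists for neighbouring tissue, 2 (liver and striated muscle) lay beyond the central 95% of random lists with most tested members moved the same way by over 1. Different amounts of neighbouring kidney, liver, muscle or fat in the dissections would give this. The liver list is Mir122 alone, so that gene by itself met the rule. Of 11 striated muscle genes, 4 were tested. Of these, 3 were higher in replicate 2 by over 1, and Mir1b (13 and 2 counts) was lower by over 1. The rest of the list had too few counts to be tested. In the either-strand column striated muscle lay at percentile 97.0, inside the central 95%. Mir192 and Mir194-2, also abundant in liver, were higher in replicate 2. Mir194-2 shares its mature form with Mir194-1, which was lower in replicate 2 with 39 counts and 1 count, so the level of Mir194-2 is uncertain. Mir215 (287 counts and 1 count) was lower too. Mir148a, chosen after its values were seen and also made in liver, had a log2 ratio of -1.50. The erythroid median of -2.21 may reflect less blood in replicate 2, but it rests on Mir451a and Mir144 of 1 cluster (Mir144 alone in the either-strand column). Mir486 had a log2 ratio of 0.64 from 49 and 33 counts and was not called. It shares 20 bases with another precursor, so its level is uncertain. Mir223 of leukocytes had 1.48. A difference between the animals themselves was not tested and stays open.

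The differences of other genes had several possible sources. Of 269 genes with at least 50 counts in both libraries, 79.2% passed the adjusted p, above the cut-off set beforehand. Their log2 ratios had an SD of 0.865. The exact test allows for counting error of independent reads only, and reads are not independent molecules. With 1 library per animal, it sets a spread between single samples against technical noise. Its outcome was therefore classed as unable to decide on counting error as the whole source. Genes of lower count were not covered, and the test does not tell which source was at work. A straight-line trend with precursor GC content as the whole cause is argued against by the 0.245% of variance it accounted for (bootstrap 95% interval 0.000653 to 2.38%). Spearman rho was 0.00455 (permutation p = 0.938) and Pearson r was 0.0495 (permutation p = 0.405). Genes of 1 cluster had like ratios, with an intraclass correlation of 0.442 over 142 genes in 40 clusters (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give) and 0.320 without Mir144 and Mir451a, which argues against counting error alone, as that is independent between genes, and transcription may contribute. Genes with the same number in their names on separate transcripts also had like ratios. Their mean difference was 0.54 against 0.88 in shuffled pairs (108 pairs of 76 genes, one-sided permutation p = 0.0025). It was 0.45 in 27 pairs of 32 genes without shared sequence (p = 0.0038, permutation). Capture that depends on the mature sequence may therefore contribute as well. A gene can recur in several pairs, and how far single families carried the result was not measured. These results do not separate the sources, since related genes can also be regulated alike.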
